A study of Mus musculus with 12 samples.

How the data were processed

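Gene expression was measured in mouse embryonic fibroblasts (MEFs), primary connective tissue cells grown from embryos, on 12 1-colour Agilent oligonucleotide arrays. The labels give 3 genotypes of SIRT1, an NAD-dependent protein deacetylase: wild type (WT), heterozygous (Het) and knockout (KO), with 4 arrays each, and call the cells female. Per the labels' protocols the cultures were kept in medium with 25 mM glucose, 4 mM glutamine and 10% fetal bovine serum, and 500 ng of RNA was labelled per array. Replicate numbers were taken from the labels: 1, 2, 3 and 5 for WT, and 2, 3, 4 and 5 for Het and KO. The sample titles also hold a second code, which differs between the genotypes at number 5 and is not explained. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

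Per the file headers, the authors scanned each array and extracted its spots with Agilent Feature Extraction, version 9.5 in the submitters' processing notes. The deposited spot tables hold the processed signal as an intensity on a linear scale, after background subtraction by that software and before any scaling between arrays. The deposited series table was compared with them spot by spot and holds the same processed intensity, with a largest relative difference of 0, so it is on a linear scale, uncentred and unscaled. Each array has 45018 spots, of which 43379 are not controls. The arrays lay on 4 slides, read from the names of the deposited spot data, and were scanned on 1 day. Slide 1 held Het replicates 3 and 4 and KO replicate 3, slide 2 held WT replicate 1, slide 3 held WT replicates 2 and 3, Het replicate 2 and KO replicate 2, and slide 4 held WT replicate 5, Het replicate 5 and KO replicates 4 and 5.

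Control spots and spots marked as outliers by the extraction software were left out, spots of the same probe were averaged, and 41174 probes remained. The log2 of the processed signal minus the array's 75th percentile over non-control probes is the level used throughout, so a level of 0 equals that percentile. Among different probes with the same gene name the probe with the highest mean over the 12 arrays stood for the gene, and the fold change of another tested probe is given for genes named by size where it differs by over 2-fold. A feature was tested if its spot was well above background, by the extraction software's own call, on all arrays of at least 1 genotype, which left 16987 of 27962 named features. A gene that was not well above background on any array of a genotype has only a bound there. It is given as at least N-fold, computed as the brighter genotype's mean over its arrays against the dim genotype's mean of, per array, the higher of the lowest signal among probes well above background and the dim probe's own signal. For the sex genes, compared between single arrays, the same floor was used for each array where the gene was not well above background. For genes named by size and well above background on only some arrays of a compared genotype, the number of those arrays is given, and the fold rests partly on signals near background.

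Gene names on the array are those of its design. Of the 41174 probes, 22951 were named through their accession in a RefSeq table of assembly GRCm38, 6659 through a current symbol and 3109 through a synonym, and 8455 were not matched and keep the array's name. Where the current symbol differs, the array's name is given in parentheses. Coordinates are those of the array files, on build mm7, and no gene model of that build was used here.

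Genotypes were compared with limma 3.58.1 in R 4.3.3 (with version 1.17.8 of data.table and 2.0.0 of jsonlite), in 1 fit of all 12 arrays with group means and empirical Bayes moderation. The contrasts were Het minus WT, KO minus WT, KO minus Het, and Het minus the mean of the WT and KO groups. A feature was called when its Benjamini-Hochberg adjusted p was under 0.05. Values of single probes were also compared with exact two-sided permutation tests. Sets of genes were tested against all other tested features with limma's camera at a preset correlation of 0.01 between genes, adjusted over 36 lists within a comparison. The same lists were tested with an estimated correlation and with fry, which asks whether a list's genes move on balance 1 way. Both were run on the main fit only, so list p values with a block or without an array keep the preset correlation. Members past the threshold were counted over all features and adjusted over the list alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

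The groups, contrasts, tests, gene lists, naming rule and all alternatives but 3 were fixed before the data were examined. The 3 later alternatives concern the arrays numbered 3: leaving them out, fitting them as a block, and averaging the other arrays of a genotype into 1 sample. Named genes are, for each of the comparisons between 2 genotypes, the 12 with the largest rise and the 12 with the largest fall among called features with a gene symbol whose genotypes did not overlap on any array, and the 8 largest each way for Het against the mean of WT and KO. Added to these are up to 4 members with the smallest p of each described list, the sirtuins, and genes that tell the sex of cells. Described lists are those with an adjusted p under 0.05 in any comparison and a fixed set on metabolism, the cell cycle, p53 and sirtuins. RIKEN clones, predicted genes and unnamed accessions were counted and not named, and 3 genes chosen by the rule are counted but not reported here.

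The fixed alternatives were normexp background correction with an offset of 50 and quantile normalization, quantile or median scaling, the unscaled series table, no filter or a filter on all 12 arrays, every probe separately, slide as a fixed or random block, replicate number as a block, only the groups compared, trended robust moderation, array weights, a minimum of 1.5-fold, and leaving out each array. The pipeline was tested on simulated data with 16987 features, drawn independently per array from the means and residual spread of all 12 arrays, with changes set in KO. For KO against WT, 31 of 100 features changed by 2-fold and 89 of 100 changed by 4-fold were called, with 3 false calls. The simulated arrays shared no structure such as that of number 3, so these false calls do not measure the error rate of the real comparisons. The number of arrays limits the precision. Well above background were 26013 to 28245 non-control spots on the arrays of slides 1 to 3 and 33499 to 33921 on the arrays of slide 4.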

Results

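Expression profiles of SIRT1 WT, Het and KO MEFs were compared on 4 arrays per genotype. Levels are log2 signals relative to the 75th percentile of each array, given as mean ± SD over the 4 arrays of a genotype, and differences between genotypes are log2 fold changes with their standard error (SE). The median difference over all tested features was 0.08 for Het against WT, 0.08 for KO against WT, −0.02 for KO against Het and 0.05 for Het against the mean of WT and KO. On the unscaled signals these medians were −0.16, 0.09, 0.23 and −0.20, so all changes below are relative to the scaling of the arrays.

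The targeted gene was read by 2 probes on chromosome 10. At the probe spanning 62838289 to 62838348, Sirt1 stood at 0.36 ± 0.21 in WT, 0.37 ± 0.03 in Het and −0.47 ± 0.29 in KO cells. KO cells had 56.4% of the WT signal (−0.83, SE 0.17, exact two-sided permutation p = 0.0286, the smallest possible with 4 against 4 arrays; limma adjusted p = 0.0361) and 56% of the Het signal (−0.84, SE 0.17, exact p = 0.0286, limma adjusted p = 0.0445). Het and WT cells differed by 0.01 (SE 0.17, exact p = 0.971). At the probe spanning 62855795 to 62855854 the levels were 0.79 ± 0.24 in WT, 0.87 ± 0.34 in Het and 0.81 ± 0.41 in KO, with 0.08 for Het against WT (exact p = 0.714) and 0.02 for KO against WT (exact p = 0.971). The labels do not say which part of Sirt1 was deleted, so a probe outside the deleted part checks nothing. The limma adjusted p values of single probes come from a fit of every probe separately. In the main fit, with 1 probe per gene, the second probe stood for Sirt1. There KO against WT had 0.02 (limma adjusted p = 0.982) and KO against Het −0.06 (0.971). Sirt1 is therefore not among the called features of the main fit, and the list tests used the second probe. With slide as a block the KO differences at the first probe were −0.80 against WT (SE 0.21, limma adjusted p = 0.179) and −0.80 against Het (SE 0.19, limma adjusted p = 0.166). In the limma test KO against WT passed without the array labelled WT replicate 3 (adjusted p = 0.00743), Het replicate 3 (0.0415) or KO replicate 3 (0.0277), and lost the call without any 1 of the other 9 arrays (adjusted p 0.0568 to 0.144). KO against Het passed without the same arrays (0.0189, 0.0481 and 0.0316) and lost the call without any of the other 9 (0.0551 to 0.175).

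Genes that tell the sex of cells set 1 array apart. Xist, the noncoding RNA of the inactive X chromosome, was at −2.94 on the array labelled WT replicate 3 and at 1.66 to 3.42 on the other 11 arrays, 24.3-fold below the lowest of them. Its antisense gene Tsix was at −8.20 there and at −5.10 to −3.37 elsewhere, at least 2.08-fold below the lowest, as it was not well above background on this array. The Y-linked genes Ddx3y (1.04), Eif2s3y (0.92), Kdm5d (Jarid1d on the array; −0.96) and Uty (−3.59) were 41.8-fold, 28.5-fold, at least 23.1-fold and at least 3.74-fold above the highest other array. Uty was well above background on 0 of the other 11 arrays, Kdm5d on 1, Ddx3y on 4 and Eif2s3y on 5. Usp9y and Sry were well above background on 0 arrays, and Zfy1 on all 12. The cells are female in the labels, and the sex genes of this array contradict its label; it was kept in its group and is named by its label, WT replicate 3.

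**Figure D1:**
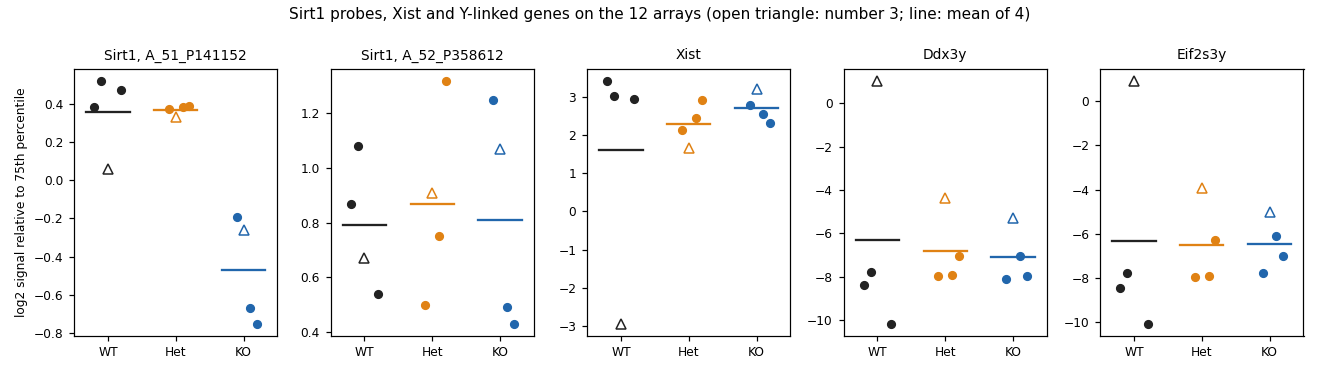
Level on each array (y axis, log2 signal relative to the 75th percentile) of both Sirt1 probes, Xist, Ddx3y and Eif2s3y in WT, Het and KO cells (x axis); points are arrays, open triangles the arrays numbered 3, and lines the means of 4 arrays. Xist is at −2.94, Ddx3y at 1.04 and Eif2s3y at 0.92 on the array labelled WT replicate 3.

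The arrays numbered 3 also stood apart in Hox genes, which set position along the body axis in the embryo. In each of the 3 genotypes, 98 of the tested features (0.58%) lay beyond every other array of the genotype on number 3, in the same direction and over 4-fold from the mean of those arrays, 44 lower and 54 higher. They include 11 of the 26 Hox genes tested (42.31%, Fisher's exact p = 9.51e-19, odds ratio 141): Hoxb4, Hoxb5, Hoxb6, Hoxb7, Hoxb13, Hoxc6 and Hoxc9 were lower, and Hoxa13, Hoxd8, Hoxd9 and Hoxd13 higher. These 11 genes are named, and the Fisher test was chosen, after their values were seen. That test treats genes that moved together, such as Hoxb4 to Hoxb7, as independent. With 1 array numbered 3 per genotype, its p measures no spread between samples. Correlations between arrays of the same genotype were 0.97 to 0.998 without number 3 and 0.925 to 0.969 with it. Those between genotypes were 0.952 to 0.976 without number 3 and 0.957 to 0.976 among the 3 arrays numbered 3. KO replicates 4 and 5, on the same slide, correlated at 0.998, with 87 features over 2-fold apart. They were kept as 2 samples because the labels name them so, and whether they come from separate cultures is open.

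**Figure D2:**
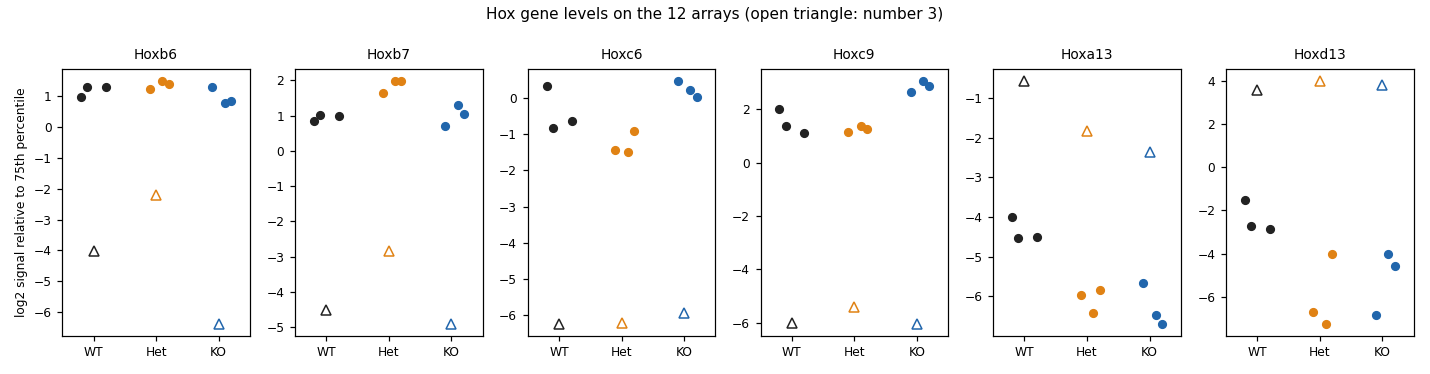
Level (y axis, log2 signal relative to the 75th percentile) of Hoxb6, Hoxb7, Hoxc6, Hoxc9, Hoxa13 and Hoxd13 in WT, Het and KO cells (x axis); points are arrays and open triangles the arrays numbered 3. The open triangles lie below the other arrays of each genotype in Hoxb6, Hoxb7, Hoxc6 and Hoxc9 and above them in Hoxa13 and Hoxd13, among the 11 Hox genes over 4-fold from the mean of the other arrays in all 3 genotypes.

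In Het cells, Peg3, a zinc finger protein expressed from the paternal allele, was among the transcripts furthest below WT. Its level was −0.32 ± 1.05 in WT and −7.10 ± 1.10 in Het (−6.78, SE 0.85, 110-fold, limma adjusted p = 0.00832, n = 4 per genotype). Another probe gave −5.17. It was well above background on 2 of 4 Het arrays. Tbx20, a T-box transcription factor of the developing heart, was at least 40.1-fold lower (adjusted p = 0.0196), with 0 of 4 Het arrays well above background. Lipoprotein lipase (Lpl) fell by 3.87 (SE 0.57, 14.6-fold, adjusted p = 0.016) and the smooth muscle calponin Cnn1 fell by 3.72 (SE 0.56, 13.2-fold, adjusted p = 0.0183). Prdm16, a regulator of brown fat identity, rose from −5.06 ± 1.90 to −0.21 ± 0.27 (4.86, SE 0.74, 28.9-fold, adjusted p = 0.0185, 3 of 4 WT arrays well above background), and the early B-cell factor Ebf3 rose by 3.22 (SE 0.46, 9.31-fold, adjusted p = 0.0154).

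Other large rises in Het cells were those of the synaptotagmin Syt13 (5.40, SE 0.97, adjusted p = 0.0371; 1.58 at another probe), Sh2d1b1 (4.10, 17.1-fold, 0.0403) and the cytochrome P450 Cyp4f14 (3.53, 11.5-fold, 0.0286), each with 3 of 4 WT arrays well above background, and the homeodomain-only protein Hopx (Hod on the array; 3.47, 11.1-fold, 0.0188). The simple epithelial keratin Krt8 (3.36, 10.3-fold, adjusted p = 0.0387) and the galectin Lgals2 (3.18, 9.05-fold, 0.0403) rose from WT levels well above background on 1 and 2 of 4 arrays. The secreted metabolic hormone Fgf21 rose by 3.25 (SE 0.60, 9.5-fold, adjusted p = 0.0399), Osr2 by 3.18 (9.09-fold, 0.0341) and Akr1c14 by 3.04 (8.22-fold, 0.016). Further falls were those of Ptprq (−4.22, adjusted p = 0.0403), Jph2, a junction protein of muscle (−4.19, 0.0473), the limb homeobox gene Shox2 (−4.19, 0.0341), Pde1a (−3.79, 0.0403; −5.42 to −4.95 at other probes), Amigo2 (−3.51, 0.0491), Cpz (−3.20, 0.0483) and Dock10 (−3.20, 0.0403). In Het cells Ptprq, Cpz and Dock10 were well above background on 1 of 4 arrays, Amigo2 on 2 and Shox2 on 3. The mesothelial gene Upk3b was at least 2.51-fold lower (adjusted p = 0.0409), with 0 of 4 Het arrays well above background. Among the sirtuins, mitochondrial Sirt3 rose from 1.34 ± 0.12 to 1.99 ± 0.11 (0.66, SE 0.13, adjusted p = 0.0418). Sirt4 differed by 0.38 (adjusted p = 0.238), Sirt5 by 0.36 (0.299), Sirt2 by 0.00 (0.996), Sirt6 by −0.25 (0.668) and Sirt7 by 0.01 (0.99). The call of Sirt3 held when WT replicate 3 was left out and was lost without any 1 of the other 11 arrays (adjusted p 0.0519 to 0.148) and with slide as a block (0.64, SE 0.18, 0.228).

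In all, 199 features were called between Het and WT by limma, 114 up and 85 down (57.3% up), 153 of them by at least 2-fold. On the unscaled signals 79 were called, 17.7% of them up. The genotypes did not overlap on any array in 9.27% of tested features, against 2.86% by chance for independent arrays. Arrays as alike as Het replicates 4 and 5 (correlation 0.994) may not be independent, and chance would then give more. The filter can also raise that share, because a feature may enter through the 1 genotype in which it is high. With slide as a block 31 were called, 25 of them among the 199. The median absolute log2 fold change of the 199 was 1.49 without the block and 1.55 with it, while the median SE rose from 0.27 to 0.32 and the residual degrees of freedom fell from 9 to 6. The count was 33 with no filter on dim probes, 82 with replicate number as a block, 0 with that block over numbers 2, 3 and 5 (1953 at an unadjusted p under 0.05) and 4842 with array weights. The count was 127 without WT replicate 1, 23 without WT replicate 2, 1476 without WT replicate 3 and 41 without WT replicate 5. Among Het arrays it was 17 without Het replicate 2, 369 without Het replicate 3, 21 without Het replicate 4 and 22 without Het replicate 5. It was 48 without KO replicate 2, 39 without KO replicate 4 and 38 without KO replicate 5. Of the 24 genes named by size, Peg3 alone was called without every 1 of the 12 arrays in turn. Called among the 24 were 15, 1 and 8 without WT replicates 1, 2 and 5, 1, 22, 1 and 1 without Het replicates 2, 3, 4 and 5, and 10, 22, 9 and 9 without KO replicates 2, 3, 4 and 5, with 7 under the slide block.

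Gene groups were tested against all other tested features. Interferon response genes were higher in Het cells, 32 of 33 members, with a median of 1.09 (camera adjusted p = 5.15e-06; adjusted p = 0.651 with an estimated correlation between genes). No member passed, 0 over all genes and 0 adjusted over the list alone. Rtp4 had 1.13 (SE 0.38, adjusted p = 0.178), Parp14 1.46 (SE 0.52, 0.195) and Ifi44 2.09 (SE 0.74, 0.195). The medians of the list were −1.76 on WT replicate 2 and 1.34 on Het replicate 2, and −0.24 and −1.01 on WT and Het replicate 3. Within slides 3 and 4 the list's median difference was 2.25 and 1.21, and with slide as a block 1.58 (adjusted p = 1.55e-12). Myofibroblast and TGF-beta response genes were lower, 26 of 31 members, with a median of −0.49 (adjusted p = 5.15e-06; 0.277 with an estimated correlation). Cnn1 was called down over all genes (0 up, 1 down), against 2 down and 0 up adjusted over the list alone. Connective tissue growth factor Ccn2 (Ctgf) had −2.55 (SE 0.60, adjusted p = 0.0684) and Tgfbi 2.63 (SE 0.78, 0.125). The list's median was −0.48 and −0.55 within slides 3 and 4 and −0.56 with the block (adjusted p = 0.000608). The call of Cnn1 was lost without WT replicate 2 (adjusted p = 0.0651), WT replicate 5 (0.0535) and Het replicates 2 (0.0782), 4 (0.0717) and 5 (0.0651), and with the block (−3.73, SE 0.72, 0.0966).

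Genes induced by p53 were lower in Het cells, 28 of 33, with a median of −0.63 (camera adjusted p = 0.000185; 0.651 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. Ercc5 had −1.02 (SE 0.29, adjusted p = 0.111), Fas −1.70 (SE 0.48, 0.112), Ephx1 −0.97 (SE 0.37, 0.222) and Sesn1 0.66 (SE 0.28, 0.277). The medians of the list on WT replicates 1, 2, 3 and 5 were 1.37, 0.60, −1 and 0.77. On Het replicate 3 the list stood at −0.1, above WT replicate 3 and so against the direction of the fall. It was −0.27 and −0.68 between genotypes within slides 3 and 4 and −0.59 with the block (adjusted p = 0.000662). Mesothelial, smooth muscle and pericyte markers were lower in 7 of 9 (median −0.59, adjusted p = 0.00231; 0.152 with an estimated correlation; −0.29 and −0.84 within slides 3 and 4; −0.56 with the block, adjusted p = 0.00617). Upk3b was called down over all genes (0 up, 1 down), against 2 down and 0 up adjusted over the list alone, and Mcam had −1.59 (SE 0.35, adjusted p = 0.0542). The call of Upk3b was lost without any 1 array but WT replicate 3, WT replicate 5 and KO replicate 3 (adjusted p 0.0536 to 0.142), and with the block (−3.60, SE 0.72, 0.109).

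Subunits of oxidative phosphorylation were higher in 43 of 48 (median 0.22, camera adjusted p = 0.0324; 0.805 with an estimated correlation), with 0 called over all genes and 0 adjusted over the list alone. Ndufs3 had 0.39 (SE 0.15, adjusted p = 0.244) and Ndufb10 0.49 (SE 0.21, 0.288). The list stood at a median of −0.68 on WT replicate 3. Without that array its difference was 0.05 (adjusted p = 0.856) and without Het replicate 3 0.20 (0.181). It was 0.30 and 0.07 within slides 3 and 4 and 0.20 with the block (0.0654). Its median was 0.11 with normexp (adjusted p = 0.187), 0.10 with quantile scaling (0.239) and −0.02 on the unscaled signals (0.195). Circadian clock genes were lower in 13 of 17 (median −0.28, adjusted p = 0.0451; 0.651 with an estimated correlation), with 0 called either way. Bhlhe41 had −0.76 (SE 0.24, adjusted p = 0.144). That call was lost without WT replicate 1 (adjusted p = 0.279), WT replicate 3 (0.278), Het replicates 2 (0.0552), 3 (0.0521) and 5 (0.0802), and KO replicate 3 (0.0836), with normexp (0.0793), with quantile scaling (0.0849) and with the block (−0.27, 0.0833). Within slides 3 and 4 the clock genes had −0.23 and −0.19.

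The remaining lists of metabolism and the cell cycle did not pass between Het and WT. Glycolysis genes were higher in 16 of 23 (median 0.35, camera adjusted p = 0.0522), and the pyruvate dehydrogenase kinase Pdk1 (1.03, SE 0.20, adjusted p = 0.0403) and the lactate transporter Slc16a1 (0.75, SE 0.15, 0.0403) rose, 2 up over all genes and 2 up adjusted over the list alone. G1/S and DNA replication genes were higher in 29 of 40 (0.24, adjusted p = 0.0522). The replication factor Mcm10 rose (0.82, SE 0.16, 0.0403), 1 up over all genes against 4 up and 1 down adjusted over the list alone. These calls were lost without Het replicates 2, 4 or 5, KO replicates 2, 4 or 5 or WT replicate 5 (adjusted p 0.0671 to 0.143 over the 3 genes). Those of Slc16a1 (0.0738) and Mcm10 (0.0723) were also lost without WT replicate 1, those of Pdk1 (0.103) and Mcm10 (0.0851) without WT replicate 2, and all 3 with the slide block (Slc16a1 0.71, SE 0.20, 0.206; Mcm10 0.86, SE 0.20, 0.148; Pdk1 1.25, SE 0.23, 0.0919). For glutamine metabolism the median was 0.13 (20 of 29 higher, adjusted p = 0.347), with 0 called over all genes and 2 up adjusted over the list alone. The cystine transporter Slc7a11 had 1.65 (SE 0.39, adjusted p = 0.069) and Gpt2 1.01 (SE 0.27, 0.101). The TCA cycle had a median of 0.05 and a mean of 0.01, with the test pointing down (adjusted p = 0.693), G2/M and mitosis 0.07 and 0.04, with the test pointing down (0.848), Myc targets −0.05 (0.331) and sirtuins and NAD metabolism 0.13 (0.184; fry adjusted p = 0.0128).

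In KO cells, neurotensin (Nts) rose furthest above WT, from −6.77 ± 1.04 to −0.48 ± 0.43 (6.28, SE 0.69, 77.9-fold, limma adjusted p = 0.00192, n = 4 per genotype, 2 of 4 WT arrays well above background). The galectin Lgals2 rose by 4.50 (SE 0.60, 22.6-fold, adjusted p = 0.00544, 2 of 4 WT arrays well above background), Nell2 by 3.38 (SE 0.45, 10.4-fold, 0.00552) and the PDZ and LIM domain protein Pdlim4 by 3.36 (SE 0.43, 10.2-fold, 0.0051), from 0.34 ± 0.59 to 3.70 ± 0.88. Peg3 fell by 6.96 (SE 0.85, 124-fold, adjusted p = 0.00417, 2 of 4 KO arrays well above background), to −7.28 ± 1.77, and by 3.95 at another probe (−3.95). Prdm8 fell by 4.98 (SE 0.52, 31.5-fold, 0.00188), from 0.33 ± 0.47 to −4.65 ± 1.08. The guidance ligand Slit3 fell by 4.07 (SE 0.58, 16.8-fold, 0.00793; −2.98 at another probe) and the glycoprotein Gpnmb fell by 4.04 (SE 0.53, 16.4-fold, 0.00544).

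The chemokine Cxcl14 rose by 5.06 in KO cells (SE 0.91, 33.2-fold, adjusted p = 0.0238) and Igfbp5, which binds insulin-like growth factors, by 4.14 (17.6-fold, 0.0345; 1.39 at another probe; 3 of 4 WT arrays well above background). Nebl (3.96, SE 0.56, 15.6-fold, adjusted p = 0.0078; 2.5 at another probe) and carbonic anhydrase 2 (Car2; 3.21, 9.23-fold, 0.0255) rose from WT levels well above background on 1 of 4 arrays, and Mtmr7 (3.48, 11.2-fold, 0.0115) from 3 of 4. Tmem30b rose by 3.02 (8.12-fold, 0.0163; 3 of 4 WT arrays well above background) and Fgf21 by 2.93 (SE 0.60, 7.64-fold, 0.0391). Further falls were those of Tbx20 (−6.73, SE 1.04, 106-fold, adjusted p = 0.0115; 1 of 4 KO arrays well above background), the urea transporter Slc14a1 (−6.61, SE 1.38, 0.0411), Aldh1a7 (−5.29, 0.0464), Angptl7 (−5.23, 0.0307) and the BMP family ligand Gdf6 (−5.01, 0.0433; 2 of 4 KO arrays well above background). Lrrc15 (−4.12, adjusted p = 0.0448) and Ctnnd2 (−4.05, 0.03) were also lower. In KO cells Angptl7 was well above background on 2 of 4 arrays, and Slc14a1 and Ctnnd2 on 3. Among the sirtuins, Sirt4 had 0.54 (SE 0.15, adjusted p = 0.111), Sirt3 0.20 (0.488), Sirt5 0.12 (0.789), Sirt2 −0.16 (0.779), Sirt6 −0.15 (0.846) and Sirt7 0.18 (0.612).

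Between KO and WT limma called 278 features, 165 up and 113 down (59.4% up), 208 of them by at least 2-fold. On the unscaled signals 142 were called, 57.7% of them up. The genotypes did not overlap on any array in 8.82% of tested features, against 2.86% by chance for independent arrays. KO replicates 4 and 5 (correlation 0.998) may not be independent, and chance would then give more, as it can through the filter. With slide as a block 57 were called, 48 of them among the 278, whose median SE was 0.29 without it and 0.30 with it. The count was 96 with no filter on dim probes, 115 with replicate number as a block, 9 with that block over numbers 2, 3 and 5, and 8746 with array weights. The count was 178 without WT replicate 1, 106 without WT replicate 2, 1749 without WT replicate 3 and 88 without WT replicate 5. Among Het arrays it was 167 without Het replicate 2, 136 without Het replicate 4 and 140 without Het replicate 5, and among KO arrays 92 without KO replicate 2, 517 without KO replicate 3, 51 without KO replicate 4 and 60 without KO replicate 5. Of the 24 genes named by size, 9 were called without every 1 of the 12 arrays in turn: Nts, Lgals2, Nebl, Nell2, Pdlim4, Peg3, Prdm8, Slit3 and Gpnmb. Called among the 24 were 16, 13 and 13 without WT replicates 1, 2 and 5, 19, 16 and 15 without Het replicates 2, 4 and 5, and 13, 21, 9 and 11 without KO replicates 2, 3, 4 and 5, with 8 under the slide block.

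The lists called in both comparisons with WT had the same directions. Both comparisons use the same WT arrays, so this can arise without an effect of genotype. Genes induced by p53 were lower in KO cells in 24 of 33 (median −0.74, camera adjusted p = 0.000587; 0.853 with an estimated correlation), with 0 called over all genes or adjusted over the list alone. Ercc5 had −1.01 (SE 0.29, adjusted p = 0.113) and Ephx1 −1.25 (SE 0.37, 0.121). The list had −0.41 and −0.89 within slides 3 and 4 and −0.63 with the block (adjusted p = 0.00127). Its level was −1 on WT replicate 3 and 0.17 on KO replicate 3, against the direction of the fall. Interferon response genes were higher in 29 of 33 (median 0.75, adjusted p = 0.00341; 0.879 with an estimated correlation), with 0 called either way. Isg15 had 1.21 (SE 0.45, adjusted p = 0.206) and Iigp1 1.77 (SE 0.67, 0.218). Without WT replicate 2 their median was 0.43 (adjusted p = 0.359). It was 1.07 and 0.73 within slides 3 and 4 and 1.12 with the block (camera adjusted p = 4.29e-07, again at the preset correlation). Mesothelial, smooth muscle and pericyte markers were lower in 7 of 9 (median −0.64, adjusted p = 0.0075; 0.152 with an estimated correlation; −0.28 and −0.88 within slides; −0.49 with the block, 0.00834). None of them was called over all genes (0) and 3 were down adjusted over the list alone. Upk3b had −2.50 (SE 0.63, adjusted p = 0.078; 2 of 4 KO arrays well above background) and Krt7 −2.01 (SE 0.58, 0.114). Circadian clock genes were lower in 12 of 17 (median −0.21, adjusted p = 0.0185; 0.853 with an estimated correlation; −0.35 and −0.13 within slides), with 0 called either way. They lost the call without WT replicate 1 (adjusted p = 0.281), WT replicate 3 (0.351) or KO replicate 4 (0.0573) and with the block (−0.16, 0.166).

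Imprinted genes were lower in KO cells in 14 of 25 (median −0.18, camera adjusted p = 0.00642; 0.152 with an estimated correlation). Peg3 and Impact (−2.02, SE 0.41, adjusted p = 0.0379) fell, 0 up and 2 down over all genes against 0 up and 3 down adjusted over the list alone, and Dcn had −1.98 (SE 0.53, 0.101). The list had −0.44 and −0.47 within slides 3 and 4, −0.22 with the block (adjusted p = 0.0257) and −0.25 without WT replicate 3 (0.134). Impact lost its call without any 1 array but those numbered 3 (adjusted p 0.0614 to 0.142) and with the block (−2.13, SE 0.41, 0.0793). Genes of the extracellular matrix were lower in 23 of 39 (median −0.21, adjusted p = 0.0201; 0.853 with an estimated correlation). The basement membrane collagens Col4a1 (−0.90, SE 0.14, adjusted p = 0.0115) and Col4a2 (−0.93, SE 0.15, 0.0166) fell, 0 up and 2 down over all genes against 1 up and 7 down adjusted over the list alone. Without KO replicate 4 or 5 their adjusted p was 0.0535 and 0.0598 for Col4a1 and 0.0767 and 0.0734 for Col4a2, and with the block 0.0985 (−0.79, SE 0.16) and 0.0788 (−0.91, SE 0.17). The matrix list's median was 0.11 without WT replicate 3 (adjusted p = 0.978), −0.15 without KO replicate 3 (0.0737), 0.02 without the 3 arrays numbered 3 (0.819), −0.12 and −0.09 within slides 3 and 4 and −0.01 with the block (0.142).

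Genes of fatty acid oxidation and PPAR targets were higher in KO cells in 24 of 30 (median 0.25, camera adjusted p = 0.0167; 0.853 with an estimated correlation). The acyl-CoA thioesterase Acot1 (1.44, SE 0.30, adjusted p = 0.0383) and the enoyl-CoA isomerase Eci2 (Peci on the array; 0.76, SE 0.16, 0.0459) rose, 2 up and 0 down over all genes against 6 up and 1 down adjusted over the list alone. Acadm had 0.65 (adjusted p = 0.0554) and Eci1 0.60 (0.0646). Between Het and WT 24 of 30 were higher as well (median 0.31, camera adjusted p = 0.0522), with 0 called over all genes against 6 up and 1 down adjusted over the list alone. The list had 0.22 and 0.30 within slides 3 and 4, 0.25 with the block (adjusted p = 0.0114) and 0.21 without WT replicate 2 (0.109). Eci2 lost its call without any 1 array but WT replicate 3 and KO replicate 3 (adjusted p 0.0504 to 0.178), Acot1 without any but those numbered 3 and WT replicate 1 (0.0552 to 0.144), and both with the block (0.75, SE 0.21, 0.195, and 1.69, SE 0.33, 0.0859). ATF4 targets and ER stress genes were higher in 26 of 36 (median 0.23, adjusted p = 0.0167; 0.663 with an estimated correlation). The lipoprotein receptor Vldlr rose (2.02, SE 0.20, adjusted p = 0.00183), 1 up over all genes against 7 up and 0 down adjusted over the list alone. Chac1 had 1.01 (SE 0.24, adjusted p = 0.0664). Between Het and WT 24 of 36 were higher (median 0.21, camera adjusted p = 0.0577, fry adjusted p = 0.0128). Vldlr rose there too (1.54, SE 0.20, adjusted p = 0.00964), 1 up over all genes against 8 up and 1 down adjusted over the list alone, and lost its call with the block (1.57, SE 0.25, 0.0665). The list had 0.18 and 0.22 within slides 3 and 4 and 0.24 with the block (adjusted p = 0.00834), and an adjusted p of 0.0557 without KO replicate 2. Genes of cholesterol and fatty acid synthesis were lower in 21 of 31 (median −0.19, adjusted p = 0.0118; 0.879 with an estimated correlation). None was called over all genes (0) against 1 down adjusted over the list alone, and Mvd was at −0.73 (SE 0.17, adjusted p = 0.0578). Their median was −0.30 and −0.25 within slides and −0.27 with the block (adjusted p = 0.00834). Without WT replicate 3 it was −0.04, with the test pointing up (0.909).

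Ribosome biogenesis genes were lower in KO cells in 26 of 34 (median −0.20, camera adjusted p = 0.00341; 0.879 with an estimated correlation), with Imp4 at −0.66 (SE 0.22, adjusted p = 0.169) and Utp20 at −0.87 (SE 0.33, 0.216). Myc targets were lower in 31 of 44 (median −0.19, adjusted p = 0.0116; 0.879 with an estimated correlation), with Cad, which starts pyrimidine synthesis, at −0.59 (SE 0.22, adjusted p = 0.198). Immediate early genes were lower in 23 of 28 (median −0.53, adjusted p = 0.00341; 0.879 with an estimated correlation), with Spry2 at −1.05 (SE 0.41, adjusted p = 0.226). Over all genes and adjusted over the list alone, 0 members were called in each of these lists. Ribosome biogenesis was −0.02 without WT replicate 2 (adjusted p = 0.178), −0.05 and −0.14 within slides and −0.15 with the block (0.0803). Myc targets were 0.01 without WT replicate 2 (0.489), −0.11 without WT replicate 1 (0.0579), −0.16 without KO replicate 3 (0.0865), −0.11 and −0.16 within slides and −0.14 with the block (0.0803). Immediate early genes stood at 1.89 on WT replicate 1 and −1.71 on WT replicate 3, and had −0.15 without WT replicate 1 (adjusted p = 0.868), 0.07 and −0.30 within slides 3 and 4 and −0.21 with the block (0.591). The glutamine list had 0.14 (20 of 29 higher, adjusted p = 0.471; Slc7a11 1.28, 0.136), glycolysis 0.08 (0.849), the TCA cycle a median of 0.02 and a mean of 0.00 with the test pointing down (0.674). The others were G2/M and mitosis 0.19 (0.304), sirtuins and NAD metabolism 0.02 (0.691), and G1/S and DNA replication 0.13 (0.336). In the last, Mcm10 rose (0.80, SE 0.16, adjusted p = 0.0345), 1 up over all genes and 1 adjusted over the list alone, and lost its call without any 1 array but those numbered 3 and Het replicate 2 (0.0591 to 0.138) and with the block (0.81, SE 0.19, 0.132).

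Comparing KO with Het cells, Cxcl14 was 207-fold higher in KO (7.69, SE 0.91, limma adjusted p = 0.00543, n = 4 per genotype), at −4.96 ± 2.05 in Het, where 2 of 4 arrays were well above background, and 2.73 ± 0.22 in KO. Nts rose by 5.38 (SE 0.69, 41.5-fold, adjusted p = 0.00809; 2 of 4 Het arrays well above background) and the teneurin Tenm3 (Odz3 on the array) by 3.99 (SE 0.39, 15.9-fold, 0.0032; 2.98 and 4.59 at other probes). Carboxypeptidase A6 (Cpa6) fell by 5.67 (SE 0.73, 50.9-fold, 0.00819; 3 of 4 KO arrays well above background), the microfibril protein Mfap5 fell by 4.88 (SE 0.68, 29.5-fold, 0.0101) and Prdm8 fell by 4.06 (SE 0.52, 0.008). Cnn1, low in Het cells, rose by 2.90 (SE 0.56, 7.46-fold, 0.0364).

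Further rises from Het to KO were those of Amigo2 (4.85, 28.8-fold, adjusted p = 0.0147), Mtmr7 (4.38, 0.00659), the lysosomal protease cathepsin C (Ctsc; 3.9, 0.0105), Nebl (3.72, 0.0124), arginase 1 (Arg1; 3.58, 0.034), Nell2 (3.22), the receptor Grpr (2.93) and Cd24a (2.87, SE 0.39, 7.32-fold, 0.00913). In Het cells Mtmr7, Nebl, Arg1 and Grpr were well above background on 1 of 4 arrays, Amigo2 on 2 and Ctsc on 3. Syt13 (−6.02, SE 0.97, 64.7-fold, adjusted p = 0.0163; −1.16 at another probe), cathepsin K (Ctsk; −5.12, SE 1.01, 0.0409), Sh2d1b1 (−4.41, 0.0326), the growth factor Fgf5 (−4.16, SE 0.61, 17.8-fold, 0.0118) and Galnt17 (Wbscr17 on the array; −3.88, 0.0477; −1.81 at another probe) fell, as did Prdm16 (−3.85, SE 0.74, 0.0363) and Gpnmb (−3.85, SE 0.53, 0.0101). Tnfaip8l3 was at least 7.44-fold lower in KO (adjusted p = 0.0152) and the potassium channel Kcnc2 at least 6.94-fold (0.0339), with 0 of 4 KO arrays well above background. Sirt3 had −0.45 (adjusted p = 0.172), and Sirt2 and Sirt4 to Sirt7 −0.24 to 0.17 (adjusted p 0.657 to 0.942). Myofibroblast and TGF-beta response genes were higher in KO than in Het in 25 of 31 (median 0.31, camera adjusted p = 0.000785; 0.496 with an estimated correlation), the only list of 36 called here. Cnn1 was called over all genes (1 up, 0 down), against 7 up and 0 down adjusted over the list alone. Tgfb2 had 1.89 (SE 0.42, adjusted p = 0.0668), Id3 1.81 (SE 0.40, 0.072) and Tgfb3 0.75 (0.0988). The list had 0.41, 0.50 and 0.17 within slides 1, 3 and 4, 0.16 with the block (adjusted p = 0.000706) and kept its call without each array in turn. The call of Cnn1 held without WT replicates 1 and 3, Het replicate 3 and KO replicate 3 and was lost without the others (adjusted p 0.0533 to 0.137) and with the block (2.88, SE 0.61, 0.115). Glycolysis was lower in 19 of 23 (median −0.36, adjusted p = 0.0643). The medians of the others were −0.02 for glutamine metabolism (0.884), −0.14 for Myc targets (0.173), −0.12 for G1/S (0.383), 0.06 for G2/M (0.215), −0.13 for p53 targets (0.933) and −0.11 for sirtuins and NAD metabolism (0.426). The TCA cycle had a median of 0.01 and a mean of −0.01 with the test pointing down (0.933).

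Between KO and Het limma called 169 features, 99 up and 70 down (58.6% up), 149 of them by at least 2-fold. On the unscaled signals it called 164, 81.7% of them up. The genotypes did not overlap in 10.58% of tested features, against 2.86% by chance for independent arrays. Chance gives more if arrays as alike as KO replicates 4 and 5 are not independent, and can give more through the filter. With slide as a block 80 were called, 73 of them among the 169, whose median SE was 0.34 with and without it. The count was 62 with no filter on dim probes, 10 with replicate number as a block over numbers 2, 3 and 5, and 6410 with array weights. The count was 111 without WT replicate 2, 327 without WT replicate 3 and 88 without WT replicate 5. Among Het arrays it was 44 without Het replicate 2, 396 without Het replicate 3, 35 without Het replicate 4 and 65 without Het replicate 5, and among KO arrays 43 without KO replicate 2, 390 without KO replicate 3, 37 without KO replicate 4 and 42 without KO replicate 5. Of the 24 genes named by size, 12 were called without every 1 of the 12 arrays in turn: Cxcl14, Nts, Mtmr7, Tenm3, Ctsc, Nell2, Grpr, Cd24a, Cpa6, Mfap5, Prdm8 and Gpnmb. Called among the 24 were 23, 20 and 18 without WT replicates 1, 2 and 5, 12, 13 and 16 without Het replicates 2, 4 and 5, and 14, 23, 13 and 14 without KO replicates 2, 3, 4 and 5, with 17 under the slide block.

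Genes at which Het cells departed from the mean of WT and KO included Tenm3 (−3.56, SE 0.33, 11.8-fold, limma adjusted p = 0.00236, n = 4 per genotype) and the phospholipid flippase Atp8a1 (−2.16, SE 0.19, 4.46-fold, 0.00236), both lower in Het. The signalling ligand Bmp4 was at 1.32 in WT, −0.99 in Het and 1.75 in KO (−2.52, SE 0.28, 5.74-fold, 0.00729). Endothelin 1 (Edn1; −2.38, SE 0.36, 5.2-fold, adjusted p = 0.021), Cnn1 (−3.31, SE 0.49, 9.92-fold, 0.021) and Amigo2 (−4.18, SE 0.64, 0.021) fell as well. Syt13 (5.71, SE 0.84, adjusted p = 0.021; 1.37 at another probe) and Prdm16 (4.35, SE 0.64, 20.4-fold, 0.021) rose in Het cells.

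The others named here were Sh2d1b1 (4.25, adjusted p = 0.0233), Cpa6 (3.70), Fgf5 (3.1, SE 0.53, 0.0276), Osr2 (2.99, SE 0.48, 0.0224) and Cyp4f14 (2.88, 0.029), higher in Het cells. In this comparison Syt13, Prdm16, Sh2d1b1 and Cyp4f14 were well above background on 3 of 4 WT arrays, Cpa6 on 3 of 4 KO arrays, and Amigo2 and Zbtb8b on 2 and 1 of 4 Het arrays. Tnfaip8l3 was well above background on Het arrays only (adjusted p = 0.023), and Zbtb8b (Zbtb8 on the array; −2.48) and Sorcs2 (−2.08, SE 0.32, adjusted p = 0.021) were lower. Sirt3 had 0.56 (SE 0.11, adjusted p = 0.0591) and Sirt2 and Sirt4 to Sirt7 −0.18 to 0.30 (0.396 to 0.9). Myofibroblast and TGF-beta response genes were lower in 28 of 31 (median −0.40, camera adjusted p = 1.22e-06; 0.281 with an estimated correlation; −0.43 with the slide block, 1.5e-05), with Cnn1 called over all genes (0 up, 1 down) against 0 up and 6 down adjusted over the list alone. Cald1 had −1.03 (SE 0.26, adjusted p = 0.113). Cnn1 lost its call without Het replicates 2 (adjusted p = 0.107), 4 (0.0911) or 5 (0.0628) and KO replicates 2 (0.0572), 4 (0.0513) or 5 (0.0507), and with the block (−3.30, SE 0.57, 0.0799). Interferon response genes were higher in 31 of 33 (median 0.70, adjusted p = 0.000224; 0.841 with an estimated correlation; 1.03 with the block, 1.77e-09), with 0 called over all genes or adjusted over the list alone. Bst2 had 0.78 (SE 0.31, adjusted p = 0.321). The interferon list's p with the block again rests on the preset correlation. Without Het replicate 2, where the list stood at 1.34, its median was 0.39 (adjusted p = 0.0894). Glycolysis genes were higher in 19 of 23 (median 0.27, adjusted p = 0.0254; 0.841 with an estimated correlation; 0.38 with the block, 0.000688), with 0 called over all genes against 2 up adjusted over the list alone. Slc16a1 had 0.62 (SE 0.13, adjusted p = 0.0591) and Pdk1 0.80 (SE 0.17, 0.0664). This call was lost without WT replicate 3 (adjusted p = 0.0658), WT replicate 5 (0.0526), Het replicates 2 (0.0501), 4 (0.0908) and 5 (0.0574) and KO replicate 3 (0.093), with normexp (0.0896) and with quantile scaling (0.0815). The medians of the others were 0.09 for glutamine metabolism (0.523), 0.16 for G1/S (0.0761), −0.20 for p53 targets (0.0524), 0.05 for Myc targets (0.78) and 0.11 for sirtuins and NAD metabolism (0.247; fry adjusted p = 0.0393). G2/M had a median of 0.01 and a mean of −0.02 (0.364), and the TCA cycle 0.04 and 0.01 with the test pointing down (0.824).

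Limma called 105 features for Het against the mean of the other genotypes, 52 up and 53 down (49.5% up), 88 of them by at least 2-fold, and 108 on the unscaled signals, 18.5% of them up. Het did not overlap WT or KO in 1.93% of tested features, against 0.4% by chance for independent arrays. Chance gives more if arrays as alike as KO replicates 4 and 5 are not independent, and can give more through the filter. With slide as a block 26 were called, 20 of them among the 105, whose median SE was 0.28 without it and 0.29 with it. The count was 10 with no filter on dim probes, 5 with replicate number as a block over numbers 2, 3 and 5, and 4103 with array weights. The count was 61 without WT replicate 2, 595 without WT replicate 3 and 44 without WT replicate 5. Among Het arrays it was 2 without Het replicate 2, 397 without Het replicate 3, 2 without Het replicate 4 and 12 without Het replicate 5, and among KO arrays 10 without KO replicate 2, 225 without KO replicate 3, 8 without KO replicate 4 and 8 without KO replicate 5. Of the 16 genes named by size, Tenm3 and Atp8a1 were called without every 1 of the 12 arrays in turn. Called among the 16 were 14 and 12 without WT replicates 2 and 5, 2, 2 and 3 without Het replicates 2, 4 and 5, and 3, 3 and 3 without KO replicates 2, 4 and 5, with 5 under the slide block.

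**Figure D3:**
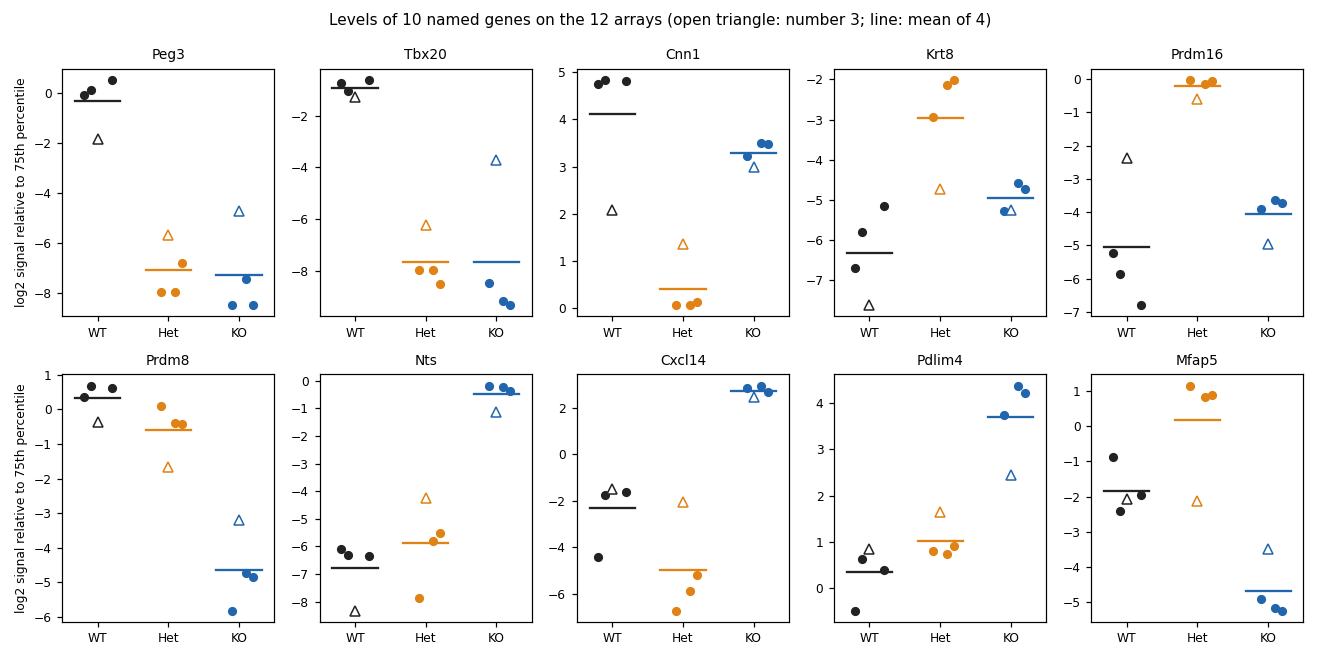
Level on each array (y axis, log2 signal relative to the 75th percentile) of Peg3, Tbx20, Cnn1, Krt8, Prdm16, Prdm8, Nts, Cxcl14, Pdlim4 and Mfap5 in WT, Het and KO cells (x axis); points are arrays, open triangles the arrays numbered 3, and lines the means of 4 arrays. Peg3 means are −0.32 in WT, −7.10 in Het and −7.28 in KO, and Prdm8 means are 0.33, −0.60 and −4.65.

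The comparisons of Het and KO with WT shared called genes. Of 114 features up in Het and 165 up in KO, 31 were the same (1.11 expected if the lists were independent), and of 85 and 113 down, 24 were the same (0.57 expected); Peg3, Tbx20, Lgals2 and Fgf21 are among them. A further 2 were down in Het and up in KO, Atp8a1 (−1.53, limma adjusted p = 0.016, and 1.26, 0.0223) and a feature with no gene name; they were singled out after their values were seen. The comparisons share the WT arrays, so some overlap arises without any effect of genotype. The fold changes of all tested features correlated at 0.51, against 0.50 (0.467 to 0.538) in 100 simulations with no effect. Their covariance was 0.19, against 0.063 to 0.078 in those simulations. The simulations gave all genotypes the same spread. WT replicate 3, however, lay over 2-fold from other WT arrays in 4808 to 5796 features, against 1720 to 2540 for Het and KO replicate 3 within their genotypes. A wider WT group alone raises the covariance, so its excess does not show an effect shared by Het and KO. With WT arrays split between the comparisons, the 6 correlations were 0.062 to 0.265 with a mean of 0.139, and the covariances 0.033 to 0.118.

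Among the 278 features called between KO and WT, the Het mean lay between WT and KO in 221, nearer WT in 110 and nearer KO in 111. It lay beyond KO in 30 and beyond WT in 27. These features were chosen for the distance between WT and KO, so a Het mean between them is expected without a graded effect. Peg3 (−0.32, −7.10 and −7.28 in WT, Het and KO) and Fgf21 (−4.27 ± 0.50, −1.02 ± 1.04 and −1.33 ± 1.17) were near the KO level in Het cells. Prdm8 (0.33, −0.60 and −4.65) and Pdlim4 (0.34, 1.02 and 3.70) were nearer WT.

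Without the 3 arrays numbered 3, an alternative chosen after the data were seen, limma called 2167 features between Het and WT, 3043 between KO and WT and 1619 between KO and Het, of 17803 tested. All 24 genes named by size in each of these comparisons were among them. Those genes were chosen for large differences without overlap on any array, and both fits use the other arrays, which favours this. In the arrays numbered 3, 51.5, 42.3 and 58.2% of all features called without them differed in the same direction (50% by chance). By over 2-fold, 16.3, 12.7 and 18.2% did so, against 14.9, 19.5 and 10.6% in the opposite direction. Among the lists, oxidative phosphorylation (0.03, with the test pointing down, adjusted p = 0.856) and the clock (−0.12, 0.649) between Het and WT lost their calls without number 3. Between KO and WT, so did cholesterol and fatty acid synthesis (−0.16, adjusted p = 0.598), the clock (−0.27, 0.235), imprinted genes (−0.34, 0.231), the matrix (0.02, 0.819) and the mesothelial, smooth muscle and pericyte markers (−0.65, 0.135). All 199 and 278 features called with 12 arrays against WT, and 167 of 169 between KO and Het, were called here too.

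**Figure D4:**
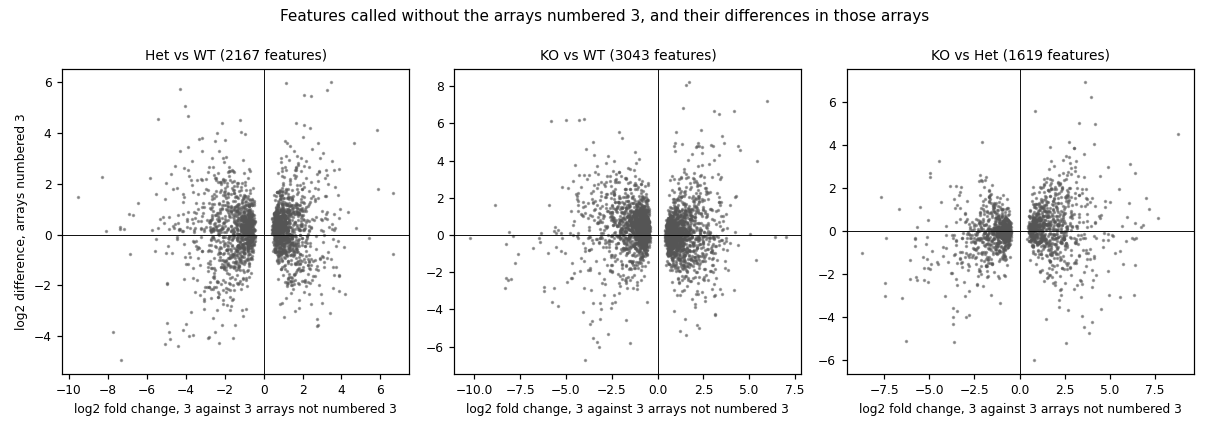
Features called without the arrays numbered 3 in each comparison of 2 genotypes (1 panel each): their log2 difference between the other arrays (x axis) against the log2 difference between the arrays numbered 3 (y axis), with points as features. The share in the same direction is 51.5% for Het against WT, 42.3% for KO against WT and 58.2% for KO against Het.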

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

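Of the tests in this part, those of a different body region, male cells, a mixture and an exchange of WT and KO, and all that leave out, block or reassign the arrays numbered 3, were chosen only after the result was seen. In groups of 4 samples, 36 of 285 had a lowest or highest array further from the rest than Dixon's 95% value of 0.829 allows. Chance marks about 1 in 20 groups in this way, or 14.2 here. Of the 36, 26 were arrays numbered 3 (11 KO, 9 Het and 6 WT).

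The arrays numbered 3 stood apart from the rest of each genotype in the same genes, with 11 of 26 Hox genes over 4-fold from the mean of the other arrays, and beyond each of them, in the same direction in all 3. Deviations of same-slide arrays of different number and genotype correlated at a mean of 0.02 (−0.18 to 0.22, 5 pairs), against 0.34 (0.22 to 0.43, 3 pairs) between arrays numbered 3. The genotype means include number 3, which pushes pairs of a number 3 array and another array down, so the 0.02 cannot exclude a slide effect. WT replicate 3, on slide 3, correlated at 0.43 and 0.22 with Het and KO replicate 3, both on slide 1. Those 2 correlated at 0.36. Cells from another body region, or a different culture or dissection behind this number, may be a candidate explanation, which the 11 Hox genes fit in a test chosen after they were seen. What the numbers stand for is not in the labels, and no biological explanation tied to genotype was tested.

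The array labelled WT replicate 3 has the sex genes of male cells: Ddx3y and Eif2s3y were 41.8-fold and 28.5-fold above the highest other array, and Xist was 24.3-fold below the lowest. Male cells in place of female cells may account for this. A mixture with a large share of female cells would keep Xist within a few-fold of the other arrays, which the 24.3-fold difference argues against. A small share of female cells stays open, as Xist was still well above background on this array. On Het and KO replicate 3, Ddx3y (−4.35 and −5.28) and Eif2s3y (−3.92 and −5.02) were well above background too, at lower levels but the highest of their genotypes, and what brought them there was not tested.

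Between 1619 and 3043 features were called without number 3. In the arrays numbered 3, the share of them in the same direction was 51.5% for Het against WT, 42.3% for KO against WT and 58.2% for KO against Het, where chance gives 50%. For KO against Het, 18.2% differed by over 2-fold in the same direction and 10.6% in the opposite one. With slide as a block, the fold changes were a median of 1.04 times those without it for Het against WT. They were 0.99 times in the other 2 comparisons. These ratios cannot decide on slide, because the features were chosen for differences in arrays that both fits use, which pulls the ratio toward 1. Slide therefore stays open. Differences between single cultures, each grown for 1 genotype, could account for such calls if the remaining replicates of a genotype share an origin, and shares of at most 58.2% fit this. An effect of genotype stays open, because number 3 has 1 array per genotype and its WT array contradicts its label. An exchange of WT and KO at number 3 cannot be told apart from the labelled order. At the responding Sirt1 probe KO replicate 3 (−0.26) differed from the lowest other WT array by −0.64, but WT replicate 3 (0.06) lay below every other WT array (0.38 to 0.52) and 0.25 above the highest other KO array, less than the SD of 0.30 of those arrays.

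Other ways of splitting the arrays were counted, with each array treated alike, although those numbered 3 share deviations (correlations of 0.22 to 0.43). Only if arrays are alike in this sense and independent is chance excluded for genes between Het and WT and between KO and Het. Between Het and WT the real split gave 199, the highest other 101, and 1 of 35 splits gave as many. Between KO and Het the real split gave 169 and the highest other 17, with 1 of 35 as many. Between KO and WT chance is not excluded, as 2 of 35 splits gave as many as 278. The other gave 541, with the arrays numbered 3 of WT and KO exchanged. For Het against the mean, 4 of 100 splits gave as many as 105, so chance would be excluded only on the same condition. The others were 470, 249 and 153. The first took the arrays of slide 4 as the group and points to a structure of the samples; with slide as a block the real split gave 26. The next took the WT arrays as the group. The condition of alike and independent arrays is not met by those numbered 3. Other arrays of the same genotype may not be independent either. KO replicates 4 and 5 correlated at 0.998, Het replicates 4 and 5 at 0.994 and WT replicates 2 and 5 at 0.992. The real split keeps such pairs together and many others part them, so these counts cannot exclude chance. Over the 6 ways of giving the arrays numbered 3 alone to the genotypes, the highest counts passed the real ones. Het against WT reached 241 (with WT, Het and KO replicate 3 as Het, KO and WT), and KO against Het reached 217 (WT and Het replicate 3 exchanged). Het against the mean reached 127 and 108 in these 2 orders, so 2 of the 6 orders passed the real 105. The 6 orders are too few for a share under 0.05. Chance is not excluded for the number of lists: 32 of 35 splits gave as many as 6 between Het and WT (highest other 15), 8 of 35 as many as 12 between KO and WT (14), 35 of 35 as many as 1 between KO and Het (14), and 94 of 100 as many as 3 for Het against the mean (19).

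Further single arrays outside their group are given as values. On WT replicate 3 they were Xist −2.94, Pde1a −3.55, Cnn1 2.08, Nts −8.32, Grpr −6.03 and Cd24a 0.60. On Het replicate 3 they were Hopx 0.55, Fgf21 −2.56, Akr1c14 −0.95, Cnn1 1.35, Dock10 −5.13, Slc14a1 −3.88, Tenm3 −0.75, Mfap5 −2.12 and Sorcs2 −1.74. On KO replicate 3 they were the cholesterol and fatty acid synthesis list 0.18, Cyp4f14 −6.16, Fgf21 −3.07, Tbx20 −3.73, Shox2 −3.46, Lpl −6.55, Pde1a −1.83, Amigo2 −2.85, Ctsc −1.06, Ctsk −1.73 and Zbtb8b −5.43. On other arrays they were Sirt6 −3.35 and Dock10 −7.98 on KO replicate 2, Uty −9.87 and Usp9y −9.74 on Het replicate 5, Sry −7.80 and the glutamine list −0.01 on WT replicate 2, Cd24a 0.40 and Cpa6 −0.56 on Het replicate 2, Cxcl14 −4.43 on WT replicate 1 and Kcnc2 −7.91 on KO replicate 4. Some of these are background readings. Uty and Usp9y in Het, Sry in WT and Kcnc2 in KO were not well above background on any array of the genotype. Nts on WT replicate 3, Lpl on KO replicate 3 and Dock10 on KO replicate 2 lay below the lowest level well above background there (−6.16, −6.25 and −6.16).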

How the results depend on the processing

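Of the alternatives here, those concerning the arrays numbered 3 were tests chosen only after the result was seen. Genes called for Het against WT, KO against WT, KO against Het and Het against the mean were 33, 96, 62 and 10 with no filter on dim probes, 31, 57, 80 and 26 with slide as a fixed block, 0, 9, 10 and 5 with replicate number as a block over numbers 2, 3 and 5. They were 4842, 8746, 6410 and 4103 with array weights, 2167, 3043, 1619 and 1532 without number 3, 580, 733, 415 and 409 with number 3 as a block, and 0 in each with the other arrays averaged. That last fit has 2 samples per genotype, 1 of them number 3, so its counts of 0 show little; at an unadjusted p under 0.05 limma gave 760, 555, 528 and 621 in it. The 0 of the replicate block over numbers 2, 3 and 5 stands beside 1953 at that p. In the comparisons of 2 genotypes alone they were 51, 118 and 290. With replicate number as a block the first 2 counts were 82 and 115, and on the unscaled signals 79 and 142. Leaving out 1 array gave 17 to 1476, 51 to 1749, 35 to 396 and 2 to 595 genes, and 5 to 12, 8 to 12, 1 to 4 and 1 to 8 lists. Deviations from the genotype means of arrays with the same number correlated at −0.04, 0.09 and 0.02 (number 2), 0.43, 0.22 and 0.36 (3), 0.03 (4) and 0.19, 0.31 and −0.04 (5).

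Lists called with an estimated correlation were 0 in each comparison, and with fry 3, 4 and 0 in those of 2 genotypes. For Het against WT, 13 were called with no filter. For KO against WT, 6 were called with array weights and 7 without number 3 and with the other arrays averaged. For KO against Het, 3 were called with no filter, 2 with the filter on all 12 arrays, 5 with the slide block, 4 with the replicate block, 3 with only the groups compared, 7 on the unscaled signals, 6 with array weights, 3 without number 3, 4 with number 3 as a block and 3 with the others averaged. For Het against the mean, 6 were called with no filter, 6 with median scaling, 6 with the slide block, 5 with the replicate block, 5 with array weights and 5 without number 3. The list test changed direction for cholesterol synthesis in KO against WT without WT replicate 3 (median −0.04; −0.30 to −0.04 leaving out 1 array), and without number 3 for oxidative phosphorylation in Het against WT (median 0.03) and the matrix in KO against WT (0.02). Medians changed sign while the test kept its direction for oxidative phosphorylation on the unscaled signals (−0.02) and, in KO against WT, the matrix without WT replicate 3 (0.11), Myc targets without WT replicate 2 (0.01), and Myc targets (0.03) and ribosome biogenesis (0.02) with the others averaged.

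At the responding Sirt1 probe KO lost the call against WT and Het with no filter (−0.83 and −0.84, adjusted p 0.0988 and 0.129), the slide block (−0.80 and −0.80), the replicate block (−0.79 and −0.84, over numbers 2, 3 and 5 −0.75 and −0.76), the unscaled signals (−0.81 and −0.58) and averaging (−0.66 and −0.75), and against WT with only the groups compared (−0.83, 0.131). Leaving out 1 array gave −0.92 to −0.73, −0.93 to −0.74 and, for Het against WT, −0.09 to 0.06, and at the other probe −0.13 to 0.14, −0.20 to 0.09 and −0.07 to 0.20. The correlation of fold changes ran from 0.40 to 0.67. The cause of these changes was not tested. Of the 88 results of genes named by size, 0 reversed. Leaving out an array cannot reverse a difference without overlap, and these genes were also chosen for large differences, so this 0 shows little. The call was the same for 84 with quantile scaling, 83 with normexp, 41 with no filter, 37 with the slide block and 87 with slide as a random block. It was the same for 44 with the replicate block, 3 with that block over numbers 2, 3 and 5, 74 on the unscaled signals, 88 with array weights and 0 with the others averaged. With only the groups compared, 48 of 72 were the same. Slide as a random block was not run for lists, scan date was not run as a block (1 scan day), and the filter on all 12 arrays leaves 33 of the 88. The signal over background limits dim genes: on slides 1 to 3 the lowest signal well above background was 28.86 to 43.05, on slide 4 8.628 to 9.764.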

Other observations

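No tests were added in this part after the result was seen, but the genes named in it were chosen after their values were seen. Outside the described lists, some members of lists that were not called differed by genotype. The Wnt ligand Wnt5a fell in Het (−1.86, limma adjusted p = 0.00219) and KO cells (−1.47, 0.00192), and the retinoic acid binding protein Crabp2 rose in Het (2.56, 0.00798) and KO cells (1.73, 0.0217). The glutathione transferase Gsta4 rose in Het (1.68, 0.0341) and KO cells (1.58, 0.0253). Their lists were not called: the smallest adjusted p was 0.0524 for Wnt targets and antagonists, 0.461 for the retinoic acid response and 0.184 for NRF2 and antioxidant genes. Het and KO were compared with the same WT arrays, so a shared direction can arise without an effect of genotype. The calls of Wnt5a, Crabp2 and Gsta4 were not followed without each array or with the slide block. Further members of uncalled lists passed and are not all named.

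The hypoxia response list was not called: in KO against Het its median was −0.36 (camera adjusted p = 0.0925; 0.947 with an estimated correlation). Of its 23 genes, 3 fell between KO and WT: adrenomedullin (Adm, −2.81, limma adjusted p = 0.00169), stanniocalcin 2 (Stc2, −1.56, 0.0107) and the oxygen-sensing hydroxylase Egln1 (−1.08, 0.0238), with 0 up over all genes, against 2 up and 3 down adjusted over the list alone (list adjusted p = 0.37). Between KO and Het, Adm (−1.85, 0.0101) and Stc2 (−2.10, 0.00431) fell too, and Stc2 was higher in Het than the mean of WT and KO (1.32, 0.021). The calls of Adm, Stc2 and Egln1 were not followed without each array or with the slide block. By camera, 15 of 36 lists were called in at least 1 comparison and 21 in none. By fry, 1 of the 21 was called, sirtuins and NAD metabolism, between Het and WT (fry adjusted p = 0.0128) and for Het against the mean (0.0393). Markers of other cell types not called had smallest adjusted p values of 0.15 (endothelial), 0.303 (macrophage and blood), 0.239 (epithelial), 0.212 (muscle), 0.163 (neural and glial), 0.165 (cartilage and bone), 0.49 (adipocyte) and 0.329 (pluripotent and germ cell). The others were 0.0753 for FOXO targets and autophagy, 0.353 for Hox genes, 0.311 for histone genes and 0.285 for NF-kB targets.

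On the arrays of slide 4, 33499 to 33921 non-control spots were well above background, against 26013 to 28245 on slides 1 to 3, and the negative controls had an SD of 2.486 to 3.034 against 10.16 to 16.94. The first 3 principal components held 29.4, 19.2 and 17.9% of the variance.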
